A study of Mus musculus with 3 samples.

How the data were processed

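The samples were 3 single-cell RNA libraries of C57BL/6 mouse forebrain at E12, 2 from the hemispheres of the control and 1 from forebrain collected after 750 µg of tamoxifen had been injected into the pregnant mouse at E10. Per the labels the tissue was dissociated with papain and the libraries were made with the Chromium v2 single-cell 3′ kit. The submitters' processing notes name Cell Ranger and the genome build mm10, with versions and parameters not given in the sources used here. The deposited matrices hold one count per gene and cell barcode, a count of unique molecular identifiers (UMIs), and the values were whole numbers, as checked on the matrices. The matrices had already been filtered to barcodes called as cells, with 10255, 11511 and 4367 barcodes in control 1, control 2 and the tamoxifen library, and a lowest total of 3040, 3090 and 4013 UMIs. Of the 27998 genes listed, 19756, 19878 and 18988 had at least 1 UMI, and 27645 gene identifiers were found in GENCODE release M21, from which coordinates were taken.

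Cells were kept with at least 1000 genes and at most 10% of UMIs from mitochondrially encoded genes, which left out 46, 69 and 11 barcodes by the limit on genes and 61, 24 and 3 by the mitochondrial limit. Doublets were scored with Scrublet as built into scanpy, and the highest scores were removed at an assumed rate of 0.8% per 1000 barcodes, which removed 841, 1060 and 153 barcodes (8.20%, 9.21% and 3.49%), while Scrublet's own threshold called 431, 661 and 10. The libraries shared 180 barcodes between control 1 and control 2, 61 between control 1 and tamoxifen, and 56 between control 2 and tamoxifen, and these were kept. The kept cells held 81047487, 77681719 and 55527409 UMIs. Counts per cell were scaled to a total of 10000 and logged, 2000 variable genes were chosen without cell cycle, sex-linked, mitochondrially encoded and ribosomal protein genes, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1 with random seed 1, which gave 29 clusters.

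Clusters were named from 16 fixed marker sets. A name needed a mean log2 fold of at least 0.5 over the other clusters, at least 3 markers past a log2 fold of 0.5, a margin of 0.35 over the next set, with a prior of 5 CPM, and at least as many of its markers as of any other set among the 10 most enriched genes detected in over 20% of cells of the cluster. A further rule would leave unnamed any cluster far below the other cells in depth with no marker among those genes. The clusters left unnamed in the main clustering fell short of the mean fold or the margin instead. These thresholds were set after the clusters had been seen, and clusters that met none stayed unnamed. The main classes were 5: cortical progenitor-like, ventral progenitor-like, intermediate progenitor-like, cortical neuron-like and ventral (GABAergic) neuron-like cells. Classes with fewer than 100 cells in a library were given as shares only. Shares carry exact Clopper-Pearson intervals and counts exact Poisson intervals at 95%.

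Counts were summed per library or class and given as CPM, UMIs scaled to an equal total, with genes of a mean of at least 20 CPM described. The size rule took genes at least 1.5-fold from both hemispheres in the same direction, and a count of 0 was set to a floor of 3 counts per library. Genes were named by a rule fixed before the data were examined: among genes of a mean of at least 50 CPM past the size rule, outside the sex-linked, haemoglobin and mitochondrially encoded genes, and further from both hemispheres than these are from each other, the 12 furthest each way in the whole library and in cortical progenitor-like cells and the 6 furthest in the other classes, and up to 4 members of each list. Genes outside that rule were named after their values had been seen. Not every gene that the rule names is reported here. For the class-specific part, the log2 ratio of a class minus the mean of the other 4 main classes was taken with a prior of 2 CPM. The comparisons, the lists, the rule and the settings listed first under alternatives were chosen before the data were examined. The lists discussed first were chosen after the values had been seen.

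There were 27 preset lists: S phase, G2/M phase, p53 targets and apoptosis, cholesterol synthesis and uptake, estrogen receptor targets and receptors, integrated stress response, heat shock and ER chaperones, immediate early genes of dissociation, glycolysis and hypoxia, nuclear oxidative phosphorylation, Notch, Wnt, Shh, and FGF and BMP signalling, proneural and early differentiation, neuronal cytoskeleton and maturation, axon guidance, radial glia identity, dorsal and ventral telencephalic patterning, early and late temporal identity of progenitors, sex-linked, haemoglobin, chromatin and DNA methylation, ribosomal proteins, and mitochondrially encoded genes. A list with at least 3 described members was summarised by the median over members of the mean log2 ratio to the hemispheres, with its percentile among 10000 random lists matched on 20 bins of expression. Phases were called from S and G2/M scores on cells thinned to 3000 UMIs, and a 3′ end was called repeated where most of the 60-base stretches of the last 300 bases of its transcript occur in transcripts of another gene.

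The size rule was tested on simulated data drawn from Poisson distributions around the mean profile of the libraries. For the whole library it called 100% of genes with a true fold of 2, 1.7, 0.5 or 0.588 (50 genes each) and 0% of 5551 unchanged genes. For a simulated class with fewer counts it called 100% at a fold of 2 and 0.5, 96% at 1.7 and 0.588, and 0% of 5576 unchanged genes. In control 2 the intermediate progenitor-like, cortical neuron-like and ventral neuron-like cells held 4133903, 4890514 and 5200143 UMIs. Cajal-Retzius-like and mesenchymal-like cells there held 1942302 and 3528661. All of these are fewer than in the simulated class, so its rates do not cover them. The simulation holds counting error only and no difference between animals. No p-values were computed, because with 1 tamoxifen library cells are not replicates of the treatment. No paired analysis was possible because the labels give the tamoxifen library no partner among the hemispheres.

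Alternatives for shares, chosen before then, were every barcode, no doublet removal, at least 2000 genes per cell, Leiden resolution 0.5 and 2, components from the control hemispheres, marker scores without clustering, and leaving out each control. For genes and lists they were median-of-ratios scaling, CPM without mitochondrially encoded, ribosomal protein and haemoglobin genes, a limit of 5 CPM, a limit of 10 UMIs, per-cell means, thinned cells in equal number, a 2-fold rule, no doublet removal, equal weight of classes, the mean of a list, and leaving out each control. For phases they were unthinned cells and a rule of 1% of UMIs in the G2/M list. Added after the data had been seen were clustering without genes that differ in every class, clustering of thinned cells, shares within a lineage, classes from the added clustering, the same lowest UMI total in all libraries, subtraction of erythroid-like UMIs, and lists without members whose 3′ end is repeated. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.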

Results

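Single-cell RNA profiles were measured in the forebrain of C57BL/6 mouse embryos at E12, the stage at which cortical and ventral progenitors begin to release neurons. There were 3 libraries. Per the labels, control 1 holds one hemisphere and control 2 another hemisphere of the same control, and the number of embryos is not given. The tamoxifen library came from forebrain of a litter whose mother had been given 750 µg of tamoxifen, an estrogen receptor modulator widely used to switch on Cre recombinase, at E10. The comparison asks how forebrain exposed to tamoxifen differs from control forebrain in its cell types and genes. The tamoxifen treatment was not replicated, so no result carries a p-value, and there is no replicate check. Values are set beside the difference between the hemispheres, which holds no variation between litters or treatments, so it can understate the spread. Every interval below is a 95% interval that covers counting error only.

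The deposited tables held 10255 barcodes and 93386855 UMIs for control 1, 11511 barcodes and 90678842 UMIs for control 2, and 4367 barcodes and 58841710 UMIs for the tamoxifen library. After filtering 9322, 10366 and 4202 cells were kept. Their median depth was 7564 UMIs and 2756 genes in control 1, 6235 UMIs and 2373 genes in control 2, and 11165 UMIs and 3281 genes in the tamoxifen library, whose cells were thus the deepest. Median mitochondrially encoded shares were 2.48%, 2.65% and 2.29%, and median ribosomal protein shares were 18.5%, 18.5% and 16.9%. Cells with at least 2 Xist UMIs and no Y-linked UMI made up 37.8%, 37.3% and 23.1%, cells with a Y-linked UMI and less Xist 35.5%, 28.8% and 48.1%, and cells with both 3.25%, 2.97% and 1.12%, so each library, those of hemispheres too, held cells of more than 1 embryo. Xist stood at 621, 567 and 331 CPM, and of the Y-linked genes Ddx3y at 22.0, 18.96 and 15.5 and Eif2s3y at 28.2, 25.3 and 32.5 CPM, so the direction of a difference in the mix of sexes remains open. Log2 ratios below are of CPM (UMIs scaled to an equal library total) in the tamoxifen library over control 1 and over control 2, in that order, and the hemisphere ratio is control 2 over control 1.

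Summed over all kept cells, the tamoxifen library had less RNA of neural progenitor regulators and more RNA of the neuronal cytoskeleton. Such sums mix classes whose shares differ between the libraries, as given below. The genes Id4 and Sox2, named next, were also at least 1.5-fold lower than both hemispheres in every main class. The shares of classes alone thus do not give their values, which do not stand for progenitors only. Id4, an inhibitor of basic helix-loop-helix factors (chromosome 13, 48261228 to 48266026, mm10), stood at 23.5 CPM (22.2 to 24.8) against 348 (344 to 352) and 315 (311 to 318), log2 ratios of -3.89 and -3.75 with a hemisphere ratio of -0.14. The SoxB1 factor Sox2 (chromosome 3, 34650405 to 34652461, inside the noncoding gene Sox2ot) had 62.4 CPM (60.3 to 64.5) against 354 and 263, log2 ratios of -2.50 and -2.08. Its relative Sox3 (chromosome X, 60891366 to 60893430) had log2 ratios of -3.12 and -2.90. The neuronal tubulin Tubb3 (chromosome 8, 123411424 to 123422015) was higher, at 2533 CPM (2520 to 2547) against 1111 and 1255, log2 ratios of 1.19 and 1.01. Rtn1 (0.73 and 0.76) and Mllt11 (0.82 and 0.73), both abundant in neurons, went the same way.

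The genes furthest below both hemispheres were Hist1h1b (-5.56 and -3.76), Id4, Hist1h1e (-5.37 and -3.65), the mRNA export factor Alyref (-2.81 and -2.72), Lmo1 (-2.78 and -2.68), Akirin2 (-2.71 and -2.65), Hist1h4d (-4.34 and -2.59), the linker histone H1fx (-2.65 and -2.58), Ppp1r14b (-2.48 and -2.41), Ube2m (-2.28 and -2.32), Hist1h2ae (-3.82 and -2.27) and Kif2a (-2.67 and -2.23). The histone genes also differed between the hemispheres, by -1.80 for Hist1h1b and -1.72 for Hist1h1e. The genes furthest above both hemispheres were Rpl10-ps3 (2.91 in both), Dynlt1c (2.44 and 2.81), Gm8797 (2.41 and 2.22), Rpl9-ps6 (2.37 and 2.18), Gm9843 (1.56 and 1.51), Wdr89 (1.67 and 1.5), Rpl27-ps3 (1.45 and 1.62), Grcc10 (1.37 and 1.26), Gm2000 (1.25 and 1.13), Gm11808 (1.27 and 1.09), Nutf2 (1.31 and 1.09) and Gm8730 (1.41 and 1.06). Of these, 11 have a 3′ end repeated in another gene and Wdr89 has none, so the counts of these 11 are uncertain, because reads of near-identical genes are hard to tell apart. Hist1h1e has such an end too.

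By the size rule, at least 1.5-fold from both hemispheres in the same direction, the tamoxifen library was higher in 120 and lower in 687 of the 5726 genes with a mean of at least 20 CPM. The same rule placed control 1 above the other libraries in 254 genes and below them in 35, and control 2 above in 4 and below in 7. Between the hemispheres 314 genes were 1.5-fold apart. These numbers describe size in these 3 libraries and are not counts of changed genes. Against control 1 alone, without control 2, they were 260 higher and 1200 lower, and a lower CPM limit or a 2-fold rule moved them by more than 1.5 times in either direction.

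The preset lists followed the same division in the whole library. All 20 measured radial glia genes were lower than in both hemispheres, with a median log2 ratio of -0.77 and a hemisphere median of -0.13. Of the neuronal cytoskeleton and maturation list, 22 of 29 members were higher than in both and 2 lower (median 0.29, hemispheres -0.06). The S phase list had 35 of 36 members below both hemispheres (median -0.62, hemispheres -0.22), led by Usp1 (-1.80 and -1.29) and Casp8ap2 (-1.99 and -1.25). The G2/M list had 41 of 49 below both (median -0.44, hemispheres -0.25), among them Mki67 (-2.30 and -1.19, hemisphere ratio -1.11) and Tmpo (-1.58 and -1.25). Each of these medians lay outside the values of 10000 random lists matched on expression, at percentile 0 or 100. Within cortical and ventral progenitor-like cells the radial glia medians were 0.01 and -0.19 and those of the neuronal cytoskeleton -0.08 and 0.06. There S phase stood at -0.09 and -0.08 and G2/M at -0.05 and -0.09. Usp1, Casp8ap2, Mki67 and Tmpo were each at least 1.5-fold lower than both hemispheres in every main class, neuron-like cells included. Their values are thus not read as fewer cycling cells. The other classes are given below.

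The Shh, Wnt and Notch lists were also lower in the whole library. The 3 measured Shh members, Smo (-1.14 and -1.03), Gas1 (-1.17 and -1.03) and Gli3 (-1.15 and -0.84), gave a median of -1.08. The Wnt list had a median of -0.81 (hemispheres 0.01), the Notch list -0.51 (hemispheres -0.07), and late temporal identity of progenitors -0.67 with 15 of 17 members below both. FGF and BMP signalling, at -0.15, lay within random lists (percentile 26.1). Lists whose hemisphere median was about as large were dorsal patterning (-0.34, or -0.16 without control 1, hemispheres -0.29), chromatin and DNA methylation (-0.36, or -0.225 without control 1, hemispheres -0.32), axon guidance (-0.23, hemispheres -0.28) and early temporal identity (-0.18, or 0.08 without control 1, hemispheres -0.24), so the direction of the last is open. Ventral patterning was 0.24 with hemispheres at -0.42, and 0.49 without control 1 and 0.08 without control 2. Proneural and early differentiation was 0.16, or 0.10 without control 1, with hemispheres at -0.07. Within cortical and ventral progenitor-like cells the medians were 0.08 and 0.13 for Notch and -0.11 and 0.07 for Wnt. Shh medians were -0.30 and -0.62, over 5 and 4 members. They lay at percentiles 6.955 and 2.49, so the value of cortical progenitor-like cells was within random lists. Late temporal identity was -0.03 and -0.21. The whole-library values of these lists thus also hold the mix of classes.

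Lists of stress and metabolism stayed near 0 in the whole library. Medians were -0.09 for p53 targets and apoptosis, -0.07 for the integrated stress response, 0.02 for heat shock and ER chaperones, 0.10 for cholesterol synthesis, 0.12 for glycolysis and hypoxia, and -0.05 for nuclear oxidative phosphorylation. All of these rested on the choice of control. Without control 1 p53 targets were at -0.14, cholesterol at 0.05 and glycolysis at 0.03, and without control 2 p53 targets were at -0.04, the stress response at -0.04, heat shock at -0.0075, cholesterol at 0.18 and oxidative phosphorylation at 0.0013. The estrogen receptor list, the receptors and targets closest to the pharmacology of tamoxifen, had 6 measured members and a median of 0.34 (0.16 without control 1, 0.51 without control 2) beside 0.28 between the hemispheres. Immediate early genes of dissociation had a median of 0.15, with Fos higher (1.92 and 2.00) and Jund lower (-2.01 and -1.88). Ribosomal protein genes had a median of -0.23 and mitochondrially encoded genes -0.31.

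**Figure D1:**
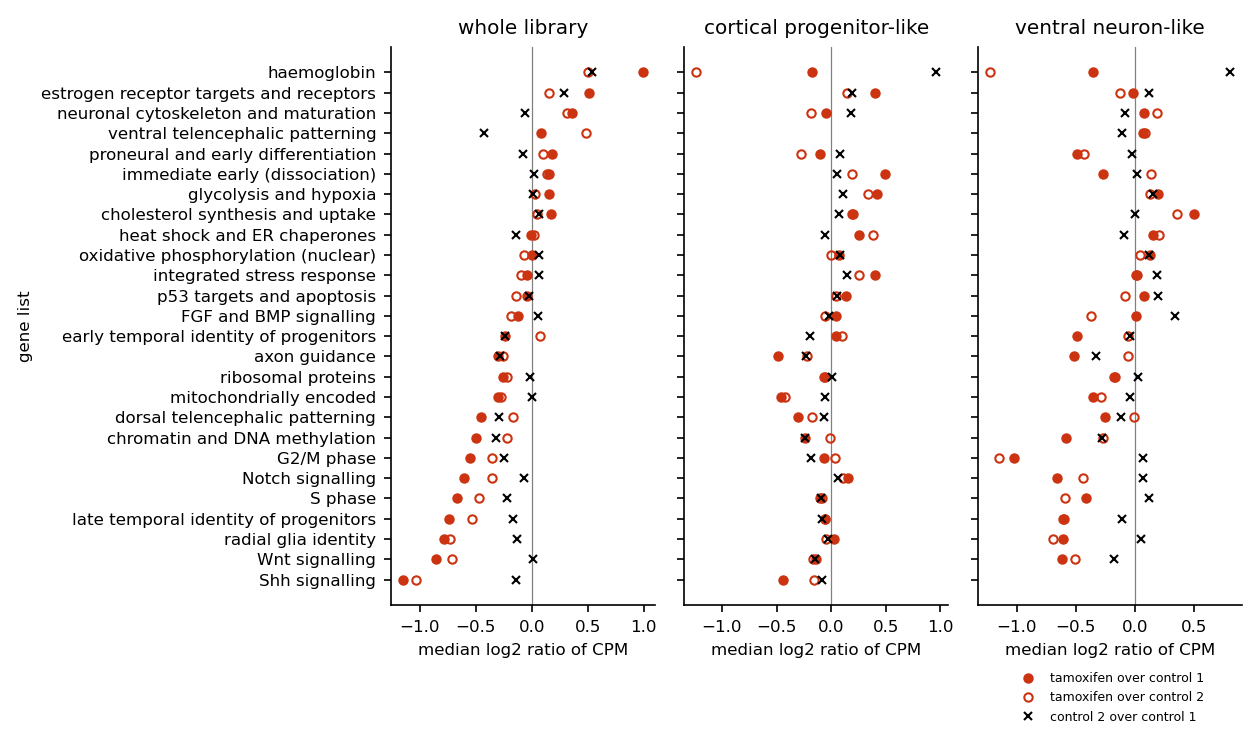
Median log2 ratio of CPM (horizontal axis) of each preset gene list (vertical axis) in the whole library, in cortical progenitor-like cells and in ventral neuron-like cells, with red points for the tamoxifen library over each hemisphere and crosses for control 2 over control 1. In the whole library the radial glia median is -0.77 and the neuronal cytoskeleton median 0.29, while in cortical progenitor-like cells the radial glia median is 0.01.

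Much of the gene-level difference was alike in every main class. Of 4506 genes measured in all 5 main classes, 33 were at least 1.5-fold higher and 268 at least 1.5-fold lower than both hemispheres in each class, against 71 that were 1.5-fold apart between the hemispheres in each class. Id4, Sox2, Alyref, Akirin2, H1fx, Lmo1, Ube2m, Kif2a, Ppp1r14b and Jund are among the lower genes, and Wdr89, Rpl15 and, with 3′ ends repeated elsewhere, Rpl10-ps3, Dynlt1c, Nutf2, Kpna2 and Rpl27 among the higher. The lower genes were also below both hemispheres in cells of other origin, in 263 of 263 measured in Cajal-Retzius-like, and 242 of 246 in mesenchymal-like cells. In erythroid-like cells 66 of 66 were below both, but there the median of all genes was -0.71, so most genes were. Without control 2 the count of higher genes was 60 and that of lower genes 576. Over 1400 genes, Pearson correlations between main classes were 0.838 to 0.963 for the tamoxifen ratio and 0.808 to 0.94 for the hemisphere ratio. Sharing between classes is thus not particular to the tamoxifen library.

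**Figure D2:**
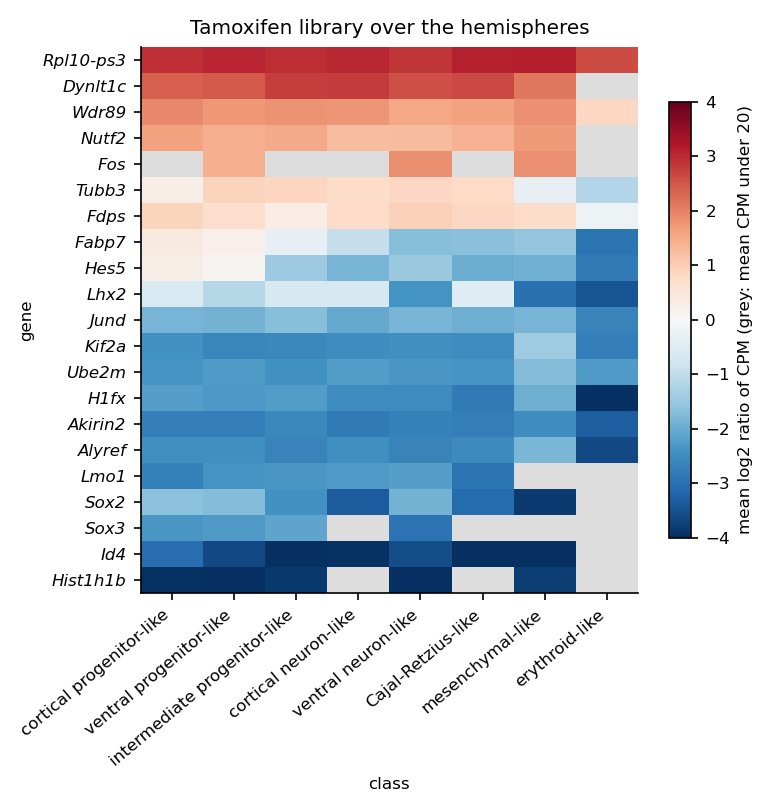
Mean log2 ratio of CPM of the tamoxifen library over the hemispheres (colour) for named genes (vertical axis) in 8 classes (horizontal axis), with grey where the mean CPM was under 20. Rpl10-ps3 is high and Id4 and Alyref low in every class measured, while Fabp7 and Hes5 are low outside the cortical and ventral progenitor-like cells.

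Cell types were named from fixed markers on clusters of all 3 libraries. Cortical progenitor-like cells made up 24.2% (23.4 to 25.1) of control 1, 19.1% (18.3 to 19.9) of control 2 and 13.0% (12.0 to 14.1) of the tamoxifen library, and ventral progenitor-like cells 22.7%, 17.2% and 15.6%. Neuron-like cells took larger shares of the tamoxifen library, at 10.1%, 7.97% and 13.2% for cortical neuron-like and 15.5%, 10.1% and 21.7% for ventral (GABAergic) neuron-like cells. Intermediate progenitor-like cells, the Eomes-expressing step between cortical progenitors and neurons, made up 6.59%, 5.73% and 7.97%, and Cajal-Retzius-like cells, the early neurons of the cortical surface, 4.09%, 3.30% and 6.09%. Diencephalic-like cells made up 1.93% of control 1, 15.8% of control 2 and 1.07% of the tamoxifen library, so the hemispheres did not hold the same mix of tissue. Cells of clusters left unnamed made up 4.94%, 5.50% and 5.81%. These were not alike either, since the unnamed cluster 28, with Gata3, Sox14 and Tal2 among its top genes, held 6, 236 and 0 cells.

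Shares within a lineage leave the diencephalic-like cells out. Of dorsal progenitor-like and neuron-like cells, progenitor-like cells made up 70.6% (69.0 to 72.2) in control 1, 70.6% (68.8 to 72.2) in control 2 and 49.7% (46.7 to 52.7) in the tamoxifen library. In the ventral lineage the shares were 59.5% (57.8 to 61.1), 63.0% (61.2 to 64.8) and 41.8% (39.4 to 44.3). Because genes that differ in a whole library can shape clusters, the clustering was repeated without them, which gave 82.2%, 82.7% and 65.1% in the dorsal and 62.4%, 64.5% and 42.7% in the ventral lineage. The smaller classes were cortical hem and choroid plexus-like (2.78%, 2.43%, 2.19%), mesenchymal and meningeal-like (1.61%, 4.52%, 6.21%), erythroid-like (4.22%, 6.04%, 5.16%), endothelial-like (0.311%, 0.617%, 0.976%), mural-like (0.290%, 0.482%, 0.143%), microglia-like (0.258%, 0.193%, 0.238%) and septal and preoptic-like cells (0.504%, 1.04%, 0.738%). Barcodes in the tables start at 3040, 3090 and 4013 UMIs, and free RNA differed between libraries, as the Fabp7 values below show. The clusters behind a class differed too, since clusters 0, 3 and 4 held 20.4%, 26.0% and 49.9% of the cortical progenitor-like cells of control 1 and 20.1%, 33.9% and 42.4% of control 2, while cluster 11 held 78.1% of those of the tamoxifen library, so this cluster may follow the library. Ventral progenitor-like cells were most often in cluster 1 (41.5%, 48.6% and 56.7%), cortical neuron-like cells in cluster 14 (79.6%, 80.4% and 60.04%), intermediate progenitor-like cells in clusters 12 and 20, and ventral neuron-like cells in clusters 17 (33.0%, 39.0% and 23.1%), 21 (30.2%, 27.7% and 42.1%) and 22.

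**Figure D3:**
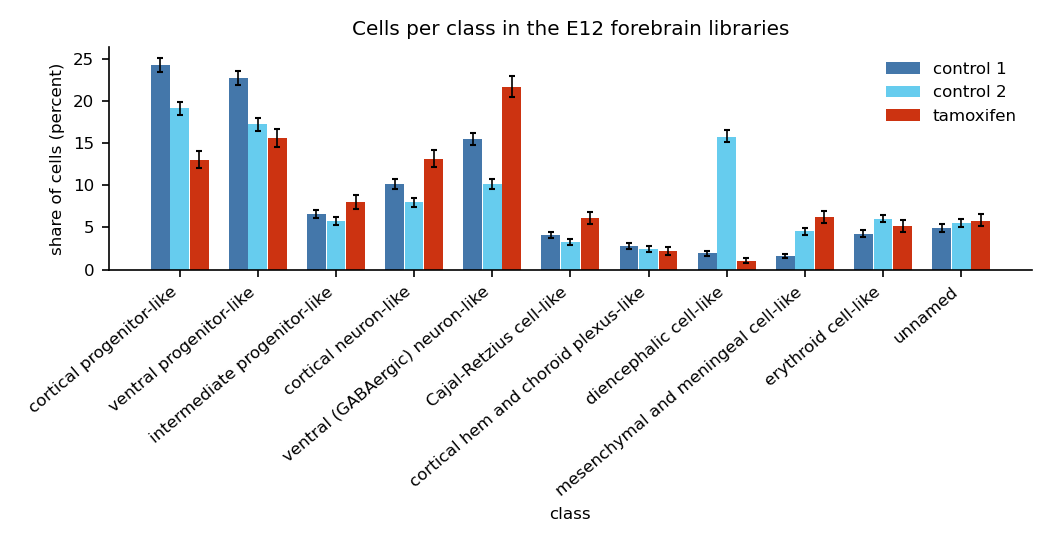
Share of kept cells in each class (vertical axis, percent) in control 1, control 2 and the tamoxifen library, with exact 95% Clopper-Pearson intervals as error bars. Ventral neuron-like cells make up 21.7% of the tamoxifen library against 15.5% and 10.1%, and diencephalic-like cells 15.8% of control 2.

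In cortical progenitor-like cells (2259, 1979 and 547 cells) the tamoxifen library had more RNA of glycolysis and cholesterol synthesis, while most progenitor lists stood near 0. The glycolysis and hypoxia list had 12 of 18 members above both hemispheres, a median of 0.42 at percentile 100 and a hemisphere median of 0.11. Pgk1 (chromosome X, 106187100 to 106203699) had 72.1 CPM (66.2 to 78.4) against 40.3 and 26.5, log2 ratios of 0.84 and 1.44. The lactate carrier Slc16a3 (1.18 and 0.77), phosphofructokinase Pfkl (0.92 and 0.73) and hexokinase Hk2 (0.72 and 0.70) were higher as well. The cholesterol list had 14 of 19 above both and a median of 0.31 (hemispheres 0.08, percentile 99.9), with Fdps (0.99 and 0.76), Mvd (0.79 and 0.44), Dhcr7 (0.52 and 0.42) and Acat2 (0.60 and 0.41). The list median was 0.25 without Fdps, whose 3′ end is repeated in another gene, 0.20 without control 1, 0.19 without control 2 and 0.13 with members of at least 5 CPM.

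Sox3 (-2.37 and -2.31), Sox2 (-1.73 and -1.52), Id4 (-2.98 and -3.13), Dmrta2 (-1.22 and -1.24), Nfix (-0.80 and -0.61) and Nfib (-0.73 and -0.43) were lower in these cells, although the medians of radial glia (0.01), S phase (-0.09) and G2/M (-0.05) were near 0. Cdc20 (1.06 and 0.93), Neurog1 (1.14 and 0.81), Kpna2 (1.29 and 1.49) and Hspa8 (0.96 and 0.89) were higher, the last 2 with a 3′ end repeated in another gene, and the neuronal Stmn2 was lower (-1.39 and -1.85). Other medians were 0.33 for the integrated stress response (hemispheres 0.15), -0.25 for dorsal patterning (-0.06) and -0.44 for mitochondrially encoded genes (-0.06). Those that rested on 1 control were immediate early genes at 0.25 (0.49 without control 2, hemispheres 0.05), p53 targets at 0.06 (0.13 without control 2, hemispheres 0.05), proneural genes at -0.23 (-0.10 without control 2, hemispheres 0.08), heat shock and ER chaperones at 0.18 (0.38 without control 1, hemispheres -0.05) and Shh at -0.30 (-0.15 without control 1, hemispheres -0.08). By the size rule 111 genes were higher and 547 lower of 5640, against 212 that were 1.5-fold apart between the hemispheres. Without control 2 these numbers were 306 and 1001. Of the genes also measured in the other main classes, 94.8% of the higher and 99.5% of the lower lay on the same side in every one of them.

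Ventral progenitor-like cells (2115, 1783 and 654 cells) differed in the factors that pattern the ganglionic eminences. Olig2 (-1.36 and -1.24) and Nkx6-2 (-1.08 and -1.15) were lower, and Gsx1 (1.44 and 1.15) and Dlx2 (0.86 and 0.63) higher, within a ventral patterning median of 0.29 (hemispheres 0.07). Gadd45g (1.02 and 0.79) and Btg2 (0.71 and 0.70), which accompany cell cycle exit, were higher, and Neurog2 lower (-1.26 and -1.21). Gsx1, Dlx2 and Gadd45g are among the 10 top genes of cluster 2, which held 7.99%, 12.2% and 18.8% of the class, and Olig2 is the top gene of cluster 5, which held 30.6%, 21.3% and 5.05%, so a shift between clusters remains open for both directions. Yet Olig2 is also a top gene of cluster 1, which held 41.5%, 48.6% and 56.7%, and Dlx2 of cluster 6, which held 19.9%, 17.95% and 19.4%. The top genes of cluster 5 include histone genes such as Hist1h1b and Hist1h1e, so this cluster may follow the library. Glycolysis had a median of 0.34 with 12 of 14 members above both hemispheres, immediate early genes 0.43 with Fos at 1.51 and 1.36, and Shh -0.62. Proneural genes had a median of 0.29 but of 0.03 without control 2 and of -0.02 with members of at least 5 CPM, so their direction is open. Fgf17 was higher (2.74 and 1.14) but also differed between the hemispheres, by 1.60. The size rule gave 107 higher and 551 lower of 5771 (hemispheres 254), or 342 and 1042 without control 2.

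Intermediate progenitor-like cells (614, 594 and 335 cells) had lower Id4 (-4.17 and -4.06), Neurog2 (-0.83 and -0.75), Neurod4 (-0.94 for both) and the Notch target Hes5 (-1.26 and -1.63). Hes5 was at 0.507, 0.517 and 0.299 UMIs per cell in them and at 0.417, 0.519 and 0.166 in erythroid-like cells, so its control values were near background. Their radial glia median was -0.62 (hemispheres 0.03), while the summed radial glia CPM had a log2 ratio of -0.10 that turned to 0.28 once the erythroid-like UMIs per cell were subtracted. The limit of this subtraction is given below. Medians were, for S phase -0.33, Shh -0.94, FGF and BMP signalling -0.51, G2/M 0.01 and neuronal cytoskeleton 0.22 (0.14 without control 1). The size rule gave 118 higher and 563 lower of 5581 (hemispheres 275), or 325 and 998 without control 2.

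In cortical neuron-like cells (942, 826 and 553 cells) genes of progenitors and of division were lower. The G2/M list had 22 of 26 members below both hemispheres and a median of -0.84 (hemispheres 0.09), with Top2a at -2.74 and -2.17 and Cenpf at -1.86 and -1.82. Radial glia genes had a median of -0.95 (-0.63 without control 1), with Sox2 at -3.39 and -3.25, and late temporal identity -0.54. Sox2 is among the genes lower in every main class, so its value is not particular to neuron-like cells. Tubb3 (0.82 and 0.67) and Nhlh1 (1.20 and 0.76) were higher, while the whole neuronal cytoskeleton list had a median of -0.02. Glycolysis and cholesterol synthesis both had medians of 0.30. The size rule gave 68 higher and 631 lower of 5723 (hemispheres 337), or 202 and 1146 without control 2. Without control 1 the higher genes numbered 106.

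Ventral neuron-like cells (1442, 1048 and 910 cells) also had division genes lower and cholesterol genes higher. The G2/M median was -1.08 (hemispheres 0.06) with 26 of 29 members below both and none above, including Top2a (-3.27 and -2.92) and Cenpf (-2.47 and -2.41). Radial glia had a median of -0.64, with Fabp7 at -1.59 and -1.82, Notch -0.62 and proneural genes -0.44, with Sox4 at -0.86 and -0.83. The cholesterol list had 15 of 18 members above both hemispheres and a median of 0.44 (hemispheres 0.00, percentile 100), with Fdps (0.96 and 0.98) and Sqle (0.62 and 0.68). Free RNA, given below, touches the radial glia genes of both neuron classes. For the G2/M list it was not separated, and Cajal-Retzius-like cells, a postmitotic type, held 19.4, 14.8 and 18.4 G2/M UMIs per cell (2839, 2604 and 1628 CPM) beside 20.1, 16.6 and 19.7 (2835, 2806 and 1692 CPM) in cortical and 19.6, 16.7 and 15.8 in ventral neuron-like cells. The lower G2/M genes are thus not read as a difference in division, and free RNA remains open for them. The size rule gave 110 higher and 671 lower of 5792 (hemispheres 347), or 325 and 1156 without control 2.

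The sex-linked list had 2 members above 20 CPM in the whole library, too few for a median, and a median of -0.34 in cortical progenitor-like cells (-0.12 without control 1). Haemoglobin genes had a median of 0.75 in the whole library beside 0.54 between the hemispheres, and of -0.66 to -0.79 in the neural classes (-0.18 to -0.36 without control 2 and -1.09 to -1.23 without control 1), where the hemispheres were 0.80 to 0.99 apart. Mesenchymal-like cells had 137 higher and 511 lower of 6090 genes, Cajal-Retzius-like cells 135 and 753 of 6074, and erythroid-like cells 13 and 842 of 1603, with the median of all genes at -0.71 in the last.

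Because so many genes differed in all classes, the class-specific part of each ratio, its excess over the mean of the other main classes, was also taken. In cortical progenitor-like cells it was at least 1.5-fold higher for 73 genes and lower for 3, against 2 between the hemispheres, and in the other classes, in the order below, 5, 16, 13 and 15 genes were so far apart between the hemispheres. Hes1 (1.23 and 1.38, against 0.08 and 0.075 in the class itself), Hes5 (1.18 and 1.47, against 0.37 and 0.13), Fabp7 (0.93 and 1.17, against 0.32 and 0.42), Ccnb1 (1.13 and 1.23, against 0.98 and 0.73) and Neurog2 (0.90 and 0.91, against -0.28 and -0.36) were among the higher. The excess of Hes1, Hes5, Fabp7 and Neurog2 thus came mostly from lower values in other classes, where free RNA counts for Hes5 and Fabp7. In the same class Stmn2 (-1.20 and -1.42), Cdk2ap1 (3′ end repeated) and Stmn3 were the lower. In ventral progenitor-like cells there were 46 higher and 12 lower. Among the higher were Dlx2 (1.23 and 1.20, against 0.86 and 0.63 in the class itself), Gsx2 (1.11 and 0.96, against 0.81 and 0.62), Dlx1 (0.90 and 0.87, against 0.32 and 0.53) and Dlx5 (1.32 and 0.82, against 0.63 and 0.51). Of these Dlx2, Gsx2 and Dlx1 are top genes of cluster 2, whose larger part of the class is given above, and also of cluster 6, which held 19.9%, 17.95% and 19.4%. Intermediate progenitor-like cells had 64 higher and 5 lower, the latter fewer than the 16 between the hemispheres. Neurod6 (1.34 and 1.12, against 0.70 and 0.34 in the class itself), Neurod2 (1.10 and 0.86, against 0.58 and 0.35) and Neurod1 (0.88 and 1.04, against 0.22 and 0.30) were among the higher. The rest of their excess came from lower values in other classes. Cortical neuron-like cells had 10 higher and 22 lower, beside 13 between the hemispheres. Nhlh1 (1.07 and 0.92, against 1.20 and 0.76 in the class itself) and Neurod6 (0.79 and 0.93, against 0.26 and 0.18) were among the higher. The excess of Neurod6 in these cells thus came mostly from lower values in other classes. Ventral neuron-like cells had 18 higher and 43 lower. The higher included Lhx8 (0.75 for both, in a class whose cluster 21 took a larger part in the tamoxifen library) and Mef2c (0.77 and 0.74, against 0.28 and 0.43 in the class itself). Lhx8 was lower in the class itself (-0.19 and -0.32), so its excess came from still lower values in other classes. The lower included Fabp7 (-1.40 and -1.57), Cks2 (-1.37 and -1.58), Ube2c and Birc5. Without control 1 the higher genes numbered 137, 103, 92, 25 and 60 in this order of classes and the lower 10, 17, 17, 34 and 70, and without control 2 the higher 91, 60, 100, 20 and 29 and the lower 5, 14, 15, 40 and 53. This measure was chosen after the ratios had been seen, and its sign was opposite to the ratio within the class for 174 of 538 named genes and 53 of 128 lists, so a gene higher by it can be lower in the class itself, as Hmga2 was in cortical progenitor-like cells (0.99 and 1.05 against -1.05 and -0.72).

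Phase calls were made on cells thinned to 3000 UMIs. Of cortical progenitor-like cells 46.3% (44.2 to 48.4) of control 1, 46.5% (44.3 to 48.7) of control 2 and 39.7% (35.6 to 43.9) of the tamoxifen library were called S, and 50.5%, 50.4% and 55.6% (51.3 to 59.8) G2/M. Without thinning the S shares were 48.4%, 48.3% and 41.7% and the G2/M shares 48.6%, 48.5% and 54.5%, and by a rule of 1% of UMIs in the G2/M list they were 49.9%, 44.8% and 51.6%. Ventral progenitor-like cells were called S in 42.1%, 41.8% and 38.1% (unthinned 42.2%, 42.3% and 41.6%), G2/M in 55.1%, 53.4% and 52.4% (unthinned 54.7%, 52.7% and 49.7%), and G1 in 2.84%, 4.82% and 9.48%. Intermediate progenitor-like cells were called S in 28.2%, 24.4% and 19.1% (unthinned 26.4%, 25.4% and 18.2%) and G1 in 25.6%, 26.6% and 35.5% (unthinned 27.0%, 26.8% and 37.0%). Summed over the S list, CPM in cortical progenitor-like cells was 5166, 4891 and 4855, and over the G2/M list 12350, 11230 and 12020, and over the S list in intermediate progenitor-like cells 4707, 4424 and 3771. No cycling is read from the phase calls alone, and free RNA, which differed between libraries, remains open as a part of them. The lists behind the calls also hold genes lower in every main class, such as Usp1, Casp8ap2, Mki67 and Tmpo, so that shift stays open too.

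Free RNA was gauged in erythroid-like cells, which lack the radial glia gene Fabp7. They held 1.34, 1.23 and 0.424 Fabp7 UMIs per cell in control 1, control 2 and the tamoxifen library, at median depths of 15149, 13050 and 37188 UMIs, and 56.7%, 58.3% and 33.6% of them had at least 1. Ventral neuron-like cells held 0.726, 0.714 and 0.377 at median depths of 5713.5, 4708 and 8792.5, which in each library is below the erythroid-like level, and cortical progenitor-like cells held 7.77, 6.20 and 13.1. The neuronal Stmn2 was at 1.17, 1.49 and 0.664 UMIs per erythroid-like cell and at 0.837, 0.983 and 0.430 per cortical progenitor-like cell. Low values of Fabp7 in ventral neuron-like cells, and of Stmn2 in cortical progenitor-like cells, are therefore at the background level in all 3 libraries. Summed over the radial glia list, the log2 ratio was -0.29 in cortical and -0.45 in ventral neuron-like cells, and 0.99 and 0.56 once the erythroid-like UMIs per cell of the same library were subtracted, a setting chosen after the data had been seen. It took cortical neuron-like cells from 2575, 2521 and 2078 CPM to 949, 713 and 1633. Because the erythroid-like level of Fabp7 exceeded that of ventral neuron-like cells, the subtraction can take off more than free RNA. The turn to positive ratios thus does not show that free RNA gave the whole deficit.

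**Figure D4:**
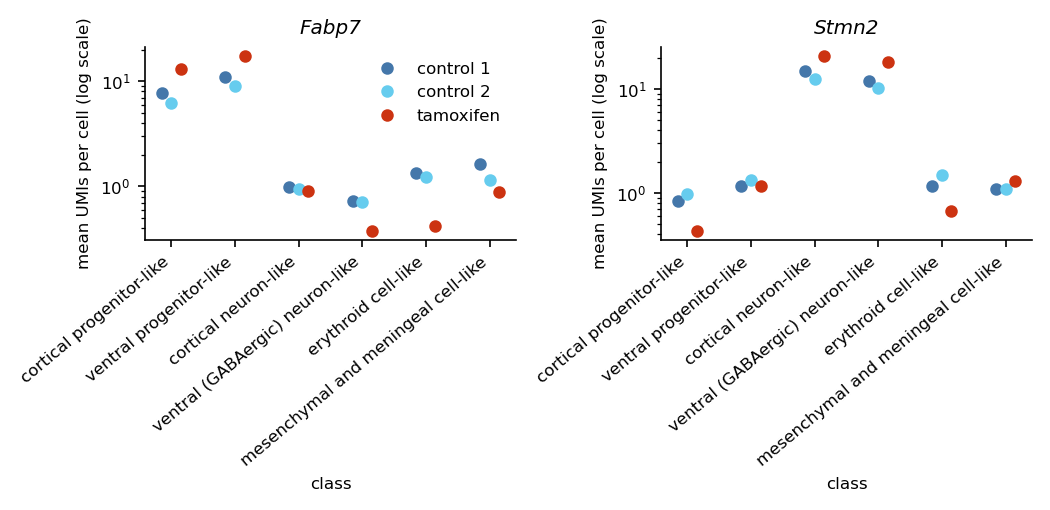
Mean UMIs per cell (vertical axis, log scale) of the radial glia gene Fabp7 and the neuronal gene Stmn2 by class (horizontal axis) in the 3 libraries. In erythroid-like cells, which lack both genes, Fabp7 is at 1.34 and 1.23 in the hemispheres and 0.424 in the tamoxifen library.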

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

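Of the tests in this part, the subtraction of erythroid-like UMIs was chosen only after the result was seen. The differences between classes below were not tested, since there is 1 tamoxifen library. The median of the Notch list stood on opposite sides in progenitor-like and neuron-like cells against both hemispheres. In the dorsal lineage their median log2 ratio was 0.15 and 0.11 in progenitor-like and -0.10 and -0.11 in neuron-like cells, a difference of -0.23, with each class within random lists (percentiles 54.6 and 25.3) and over different members. In the ventral lineage it was 0.11 and 0.13 in progenitor-like and -0.66 and -0.44 in neuron-like cells, a difference of -0.67 (percentiles 73.8 and 2.31). Proneural and early differentiation genes were at 0.03 and 0.26 in ventral progenitor-like and at -0.49 and -0.43 in ventral neuron-like cells, a difference of -0.61.

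A related pattern is that radial glia genes were lower in neuron-like cells of the tamoxifen library. A candidate explanation is free progenitor RNA in the control libraries, which predicts that cells lacking these genes show the same deficit. In erythroid-like cells the log2 ratio of the summed radial glia CPM was -2.44, or -1.10 in UMIs per cell, against -0.29 in cortical and -0.45 in ventral neuron-like cells, and subtracting the erythroid-like UMIs turned the ratios of the neuron-like cells to 0.99 and 0.56. The subtraction can take off more than free RNA, as the Fabp7 values above show, so its result does not give the size of the free RNA part. Younger neurons in the control hemispheres stay open: in the ventral neuron-like cluster of lowest radial glia level the ratio was -0.54, 120.3% of that in the class, but erythroid-like UMIs came to at least 78.0% of the controls' UMIs there, so free RNA alone could give it. The lower G2/M genes were not tested this way, because erythroid-like cells held 40.2, 33.2 and 57.2 G2/M UMIs per cell, more than neuron-like cells, and free RNA stays open for them. An effect of tamoxifen on neurons stays open and untested, and the Notch and proneural lists were not put through this test.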

How the results depend on the processing

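Of the settings below, clustering without the genes that differ in every class, thinning before clustering, the same lowest UMI total, shares within a lineage, the subtraction of erythroid-like UMIs and lists without repeated 3′ ends are tests chosen only after the result was seen. The cause was not tested for any value that moved, except where a limit or rule by its construction admits more or fewer genes. Values are the tamoxifen library minus the mean of the controls in percentage points for shares, and log2 ratios for lists.

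No share of the main classes and no phase share changed direction. The share of cortical neuron-like cells (4.12) was 2.10 at Leiden resolution 0.5, 8.07 at resolution 2, 2.29 with clustering without the genes that differ in every class, 9.30 with every barcode, 7.29 with at least 2000 genes per cell, 2.31 with the same lowest UMI total, 5.64 with thinned cells, and 3.06 to 5.19 when either control was left out. The share of intermediate progenitor-like cells (1.81) was 0.774 at resolution 0.5, 3.4 without the genes that differ in every class, 0.424 with 2000 genes per cell, 3.13 with the same lowest UMI total, 1.20 with components from the controls, and 1.39 to 2.24 when either control was left out. The share of ventral neuron-like cells (8.87) was 13.2 with 2000 genes per cell and 6.19 to 11.6 when either control was left out. The shares of cortical (-8.65) and ventral (-4.38) progenitor-like cells ranged from -11.2 to -6.07 and from -7.12 to -1.64 when either control was left out, the weaker value of both being that without control 1.

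The progenitor-like share of the dorsal lineage (-20.8) was -17.7 at resolution 0.5, -28.0 at resolution 2, -17.3 without the genes that differ in every class, -36.8 with every barcode, -22.6 with no doublets removed, -30.8 with 2000 genes per cell, -18.5 with the same lowest UMI total, -23.7 with components from the controls, -27.6 with thinned cells, -22.0 with marker scores, and -20.84 to -20.83 when either control was left out. That of the ventral lineage (-19.4) was -22.8 with every barcode, -24.2 with no doublets removed, -29.3 with 2000 genes per cell, -25.2 with the same lowest UMI total, -23.7 with thinned cells, -23.2 with marker scores, and -21.2 to -17.6 when either control was left out. The hemispheres lie so close in the dorsal lineage that small moves pass their spread.

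For phases, S in cortical progenitor-like cells (-6.73) ranged from -6.82 to -6.63 when either control was left out. G2/M in these cells (5.14) was 5.97 unthinned, 4.20 by the rule of 1% of UMIs, and 5.07 to 5.2 when either control was left out. By the 1% rule the shares were 49.9%, 44.8% and 51.6%, so the hemispheres lay further apart than this difference. S in ventral progenitor-like cells (-3.86) was -0.64 unthinned and -4.01 to -3.71 when either control was left out, and G2/M (-1.79) was -3.97 unthinned, -5.01 by the 1% rule (63.0%, 56.8% and 54.9%, where the hemispheres also lay further apart), and -2.63 to -0.94, the last without control 1.

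Counts of genes moved with the limit on expression and the fold. In the whole library the higher genes (120) numbered 285 with 5 CPM, 1013 with 10 UMIs, 68 with equal weight of the classes and 24 with a 2-fold rule, and 151 without control 1 to 260 without control 2. The lower genes (687) numbered 1317 with 5 CPM, 2674 with 10 UMIs and 250 with a 2-fold rule, and 718 without control 1 to 1200 without control 2. The limit of 10 UMIs also moved the share of higher genes among them from 14.9% to 27.5%. In cortical progenitor-like cells the higher (111) numbered 229, 660 and 29 under 5 CPM, 10 UMIs and 2-fold, and 125 without control 1 to 306 without control 2, and the lower (547) 1055, 2172 and 193, and 577 to 1001. In every main class the higher (33) numbered 62, 87 and 17, and 33 without control 1 to 60 without control 2, and the lower (268) 450, 628 and 101, and 282 to 576.

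Among lists in the whole library, S phase (-0.62) ranged from -0.67 to -0.47 when either control was left out, G2/M (-0.44) was -0.58 as a mean and -0.55 to -0.36 with either control left out, and the neuronal cytoskeleton (0.29) was 0.34 with median-of-ratios scaling, 0.33 without mitochondrially encoded, ribosomal protein and haemoglobin genes, and 0.31 to 0.36 with either control left out. Radial glia (-0.77) was -0.71 and -0.69 under these scalings, -0.98 as a mean, and -0.78 to -0.73 with either control left out. In cortical progenitor-like cells cholesterol synthesis (0.31) was 0.32 and 0.17 under these scalings, 0.13 with 5 CPM, 0.32 with no doublets removed, 0.28 as a mean, 0.25 without repeated 3′ ends, and 0.19 without control 2 to 0.20 without control 1, and glycolysis (0.42) ranged from 0.34 to 0.42. In cortical neuron-like cells G2/M (-0.84) was -0.76 and -0.86 under these scalings, -1.02 with 5 CPM, -0.90 with no doublets removed, and -0.82 to -0.80 with either control left out, and radial glia (-0.95) ranged from -0.87 to -0.63, the last without control 1. In ventral neuron-like cells G2/M (-1.08) was -1.44 with 5 CPM, -0.93 with no doublets removed, and -1.15 to -1.02 with either control left out, and cholesterol synthesis ranged from 0.36 to 0.50.

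Of list values 133 changed sign under a setting, 50 of them when a control was left out. Only 9 were counted as reversals. For list medians the rule keeps these for values on the same side of both hemispheres, beyond their difference and in the outer tails of the random lists. Class-specific medians needed a minimum size in place of the tails. The summed radial glia values were counted without these conditions. Among the sign changes not counted, in the whole library, early temporal identity (-0.18) was 0.08 without control 1 and oxidative phosphorylation (-0.05) was 0.0013 without control 2, and in ventral progenitor-like cells G2/M (-0.09) was 0.02 without control 1. Of the 9, the ribosomal protein list, with medians of -0.06, -0.05 and -0.05 in these classes, was 0.037 in cortical progenitor-like, 0.030 in ventral progenitor-like and 0.033 in cortical neuron-like cells as a mean, and 0.022 in the last with median-of-ratios scaling. The proneural list in ventral progenitor-like cells was -0.019 with 5 CPM and -0.00063 as a mean. The summed radial glia CPM was 0.28 in intermediate progenitor-like, 0.99 in cortical and 0.56 in ventral neuron-like cells after subtraction of erythroid-like UMIs, which by its construction removes a larger part of the controls.

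Of the other results, 5641 values of named genes kept within the hemisphere spread, 847 moved, and 5 changed sign, none in a gene at least 1.5-fold from both hemispheres. Of other list values 969 kept, 446 moved, some with a change of sign, and 6 were counted as reversals. Of other gene counts 57 kept and 51 moved, of other shares 88 and 23, and of other phase shares 17 and 4. Shares of small classes changed sign in 18 cases, 3 of them without a control. Genes at a few CPM in small classes rest on few UMIs and carry wide counting intervals, and the depth of the libraries sets no such limit on the genes named in the whole library.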

Other observations

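Of the tests in this part, those of another mix of tissue and of free RNA by subtraction were chosen only after the result was seen. So were clustering without the genes that differ in every class and thinning before clustering, as said above. The other tests on the genes that differ in every class were set when the names of these genes were known and the measured shares were not. Globin RNA differed in type between the libraries. Embryonic Hba-x made up 30.1% and 28.8% of alpha-type globin UMIs in the hemispheres and 21.6% in the tamoxifen library, and the adult-type Hbb-bt and Hbb-bs 10.5%, 10.9% and 14.3% of beta-type UMIs, while Hbb-bh1 made up 5.86%, 6.10% and 6.72% of the UMIs of Hbb-bh1 and Hbb-y. Hba-a1 and Hba-a2 have 3′ ends repeated in another gene.

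Many genes differed alike in every class. Among the 33 higher genes 78.8% had a 3′ end repeated in another gene, against 2.64% of other genes, a difference of 76.2 percentage points. Such an excess would be seen if reads that near-identical genes share were counted differently between libraries. The 164 genes with a mean log2 ratio of at most -1 in every main class, which need not be 2-fold below each hemisphere, argue against this cause for them, as 1.83% had such an end, a difference of -0.813 points. A-rich windows that could prime oligo-dT were as common in them as in matched genes (48.2% against 47.6%, a difference of 0.553 points, introns not searched). Free RNA stays open as a part of it: with erythroid-like UMIs per cell taken from the controls only, the median ratio of the 268 lower genes where each is highest was 62.7% of that without (-0.79 against -1.26), and 232 stayed below both hemispheres. Treatment, the mix of sexes, a library batch and a difference in processing between libraries stay open and untested.

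Progenitor-like cells took a smaller share of their lineage in the tamoxifen library. It stayed below the lower hemisphere by at least 17.1 percentage points in both lineages when clusters were made without the genes that differ in every class, and by at least 22.6 points when cells were thinned to the same UMIs. The first argues against clusters set by those genes alone and the second against depth. The new clusters were still named from all genes, among them the progenitor markers Sox2 and Lhx2, which were lower in every main class. Top genes of cluster 11 such as Gm3839 and Tuba1c were not among the genes left out. Classes that follow the library in these ways thus stay open. Because the shortfall held within each lineage, by at least 17.6 points, another mix of dorsal and ventral tissue is unlikely to be its cause. An effect of tamoxifen on neurogenesis, a difference in stage between litters, the zones of tissue recovered and unequal survival of cells stay open and untested.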
